A study of Mus musculus with 24 samples.

How the data were processed

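RNA sequencing libraries were made from 24 samples of sorted mouse hematopoietic stem cells by Smart-seq2, in which polyadenylated RNA is copied into full-length cDNA, amplified and cut by Tn5 transposase, per the labels' protocols. Such libraries do not mark the strand, so reads of overlapping or antisense genes cannot be told apart. The deposited values were whole-number counts of reads per gene, with no normalization, for 55487 Ensembl gene IDs and 5 summary entries per sample. Reads were aligned to mm10 with HISAT2 2.1.0 and counted with HTSeq 0.11.2, per the submitters' processing notes, which also name DESeq2 without a version or a design. The annotation release the authors counted against is not given in the sources used here. Symbols, coordinates and 3' untranslated regions were taken from GENCODE M21 (GRCm38), which gave a symbol to 55394 of the IDs.

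The summary entries stayed out of library sizes and tests. Reads assigned to no gene came to 3.70% to 12.0%, and ambiguous reads to 6.53% to 20.1%, as percentages computed from the deposited counts. Counts assigned to genes ranged from 9.87 M to 47.3 M (mega) per library. Reads carry no molecular identifiers, so precision and floors cover counting error only. All 42 pairs of libraries within a group differed by far more than sampling noise (lowest chi-square per degree of freedom 31.9), and each library was counted as 1 replicate. The labels do not say that the libraries of a group came from separate animals, so p-values measure the spread between these libraries, which may be partly technical.

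Each comparison was fitted on its own 2 groups with edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr, libraries were scaled by TMM, and dispersions and quasi-likelihood fits were robust. The two-sided quasi-likelihood F test was used, and genes with a Benjamini-Hochberg adjusted p under 0.05 over all genes tested were called. Standard errors were derived from the log2 fold change and the F statistic. Levels are TMM-normalised CPM, counts scaled by the effective library size, given as mean ± SD. Exceptions are all Igkc values, the ranges of Hba-a1, Elane, Xist and Ddx3y, and the highest Pde2a value, which are CPM scaled by library size only. The same holds for the lowest Pus10 value given as a percentage of the highest. A fold against a group whose libraries were all at 0 was computed against a floor of 3 counts over the group and is a lower bound.

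Of 39 gene lists fixed before the data were examined, those with at least 4 tested genes entered limma's camera (limma 3.58.1) with a preset correlation of 0.01 between genes, adjusted over the 112 list tests of the 3 comparisons. Camera with an estimated correlation and fry were run beside it. Members were also counted as changed with p-values adjusted over the list alone. The comparisons, tests, gene lists, rule for named genes and most alternatives were chosen before the data were examined.

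Genes were named by 4 parts of a rule. The first takes Pus10 and Pde2a, the gene that carries miR-139 in an intron. The second takes up to 10 called genes per direction with the largest change, mean log2 CPM of at least 3 and separated groups, or the 5 with the lowest p where fewer than 3 pass. The third takes up to 4 members with the lowest p of each list that passes and of 5 lists always shown. The last takes genes called in 2 comparisons. Genes named outside this rule are said to have been chosen after their values were seen.

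For miR-139, 3' untranslated regions were searched for matches to the seed of each strand, and the median fold change of genes with a site was set against 10000 draws of genes without one, matched on length of the region and on expression. Fold changes were correlated between comparisons, and each correlation was set against 100 pairs of splits of the samples. The fits were tested on simulated counts with known changes. At 4-fold, 100% of changed genes were recovered for PUS10-OE (14834 genes simulated), 86% for miR139-KD (13295) and 60% for Pus10-KO (14657). At 2-fold the shares were 56%, 46% and 26%. Each simulation changed 50 genes at each of 2, 4, 8 and 16-fold, all with mean log2 CPM of at least 3. So many true changes ease the adjusted cutoff, so these shares do not carry over to a fit with few or 0 calls. In the real PUS10-OE fit Pus10, 3.39-fold higher, had an edgeR adjusted p of 0.278. False calls made up 10 of 188 calls (5.32%) for PUS10-OE, 5 of 165 (3.03%) for miR139-KD and 11 of 140 (7.86%) for Pus10-KO. A simulated shift of 0.2 (log2) in genes with a seed site was recovered as 0.219 for miR-139-5p and 0.206 for miR-139-3p (permutation p = 0.0001 over 11108 genes, the smallest the draws can give).

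Alternatives were DESeq2 1.42.0, limma-voom with quality weights, other scalings, no filter, a filter of 10 CPM, the replicate number as a block, all 6 groups in 1 fit, and each library left out in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.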

Results

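Transcriptomes of sorted mouse hematopoietic stem cells (HSCs), the bone marrow cells that give rise to all blood lineages, were measured in 24 libraries that form 3 experiments. The series concerns PUS10 in HSC aging. PUS10 is a pseudouridine synthase, an enzyme that isomerises uridine in RNA. In the first experiment, cells overexpressing PUS10 (PUS10-OE, n = 3) were compared with vector controls (Vector, n = 3). In the second, cells with knockdown of the microRNA miR-139 (miR139-KD, n = 6) were compared with a non-target control (NTC, n = 6). In the third, libraries labelled Pus10-KO (n = 3) were compared with Pus10-WT (n = 3). Counts over all genes (M, mega) ranged from 34.2 M to 47.3 M in Vector, 40.9 M to 42.6 M in PUS10-OE and 11.8 M to 14.7 M in NTC. They ranged from 9.87 M to 14.4 M in miR139-KD, 14.5 M to 16.5 M in Pus10-WT and 11.9 M to 18.2 M in Pus10-KO. Between 15575 and 17879 genes were detected per library.

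Pus10 itself (ENSMUSG00000020280.12, a protein-coding gene on the plus strand of chromosome 11, 23665674 to 23732876, GRCm38) was measured first in every experiment. In PUS10-OE libraries it reached 257 ± 23.7 CPM against 75.9 ± 20.2 in Vector (SD, n = 3 each), a 3.39-fold difference. The labels do not say whether the introduced sequence is human or mouse, so these counts may miss part of it. In miR139-KD libraries it stood at 32.9 ± 7.72 CPM against 35.9 ± 6.09 in NTC (n = 6 each), a log2 fold change of -0.12 (SE 0.202, edgeR adjusted p = 0.846). In the libraries labelled Pus10-KO it was not lower than in Pus10-WT, with 35.2 ± 1.31 CPM against 28.4 ± 7.68 (n = 3 each). The log2 fold change there was 0.31 (SE 0.279, 95% interval -0.24 to 0.86, edgeR adjusted p = 0.951). The interval uses a normal quantile and is therefore somewhat too narrow for 3 libraries per group. The counts are per gene and do not show which exons they come from.

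**Figure D1:**
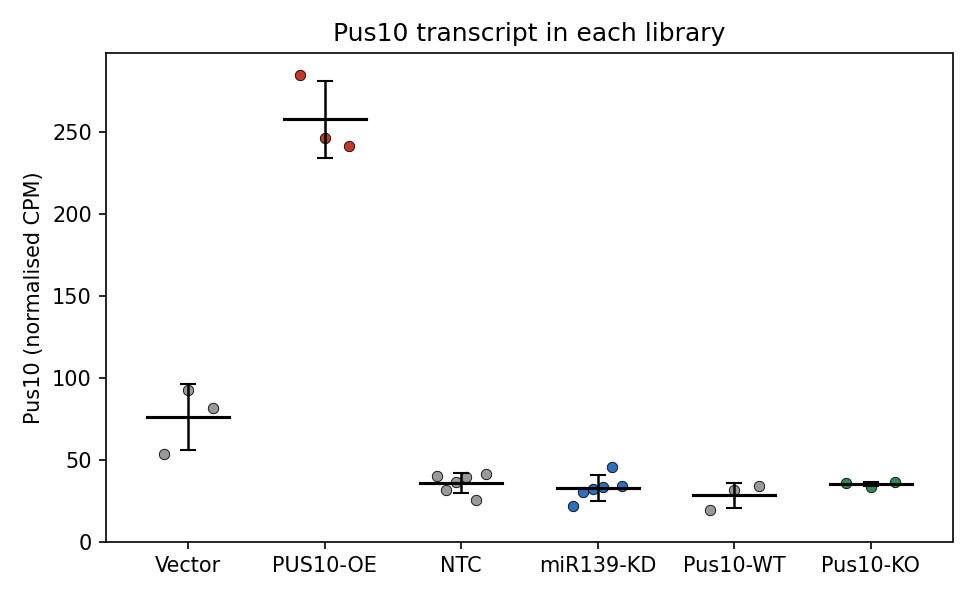
Pus10 transcript in normalised CPM (y axis, linear, from 0) for each library of the 6 groups (x axis). Points are libraries, horizontal lines group means and bars SD. The 3 PUS10-OE libraries lie above every Vector library, and the libraries labelled Pus10-KO lie at the level of Pus10-WT.

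Cells overexpressing PUS10 had a lower median for multipotent progenitor genes than Vector cells. They had higher medians for interferon, nuclear oxidative phosphorylation, ribosomal protein and HSC aging genes, whose calls were lost with an estimated correlation (adjusted p = 0.0601, 0.253, 0.509 and 0.253). Cd34, a surface marker of multipotent progenitors, stood at 549 ± 16.4 CPM against 778 ± 15.8 (SD, n = 3 each), a log2 fold change of -0.50 (SE 0.0718). Ifitm3, an interferon-induced antiviral membrane protein, stood at 1434 ± 129 CPM against 899 ± 63.6 (0.67, SE 0.0940). The nuclear noncoding RNA Malat1 stood at 362 ± 62.9 CPM against 171 ± 13.4 (1.08, SE 0.135), and the spliceosomal Snrnp70 at 67.3 ± 2.08 against 32.2 ± 4.01 (1.06, SE 0.138). None of these genes passed the test over all genes, each with an edgeR adjusted p of 0.278.

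Of 14834 genes tested, 0 passed in edgeR, while 1215 had an unadjusted p under 0.05. DESeq2 called 251 genes, limma-voom 0, and edgeR 12 after a filter of 10 CPM. Pus10, with a log2 fold change of 1.76 (SE 0.197), had an adjusted p of 0.278 in edgeR and of 7.46e-15 in DESeq2. The groups did not overlap in 2235 genes, or 15.1%, where chance gives 10%. Other genes with the lowest p were Atic, an enzyme of purine synthesis, at 0.88 (SE 0.129), and, on the lower side, the polysialyltransferase St8sia4 at -1.01 (SE 0.145), the mRNA-decay factor Zfp36 at -0.83 (SE 0.124), Txnip at -0.70 (SE 0.113) and Tor4a at -0.83 (SE 0.136).

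Of 38 lists tested, 14 passed with the preset correlation, 8 upward and 6 downward. Multipotent progenitor genes fell together (median log2 fold change -0.44, 9 of 12 negative, adjusted p = 3.95e-10), and theirs was the 1 call that held, with adjusted p = 0.0494 with an estimated correlation. Adjusted over the list alone 8 members were lower and over all genes 0, among them Cd34, Emb at -0.44 (SE 0.0854), Wfdc17 at -1.88 (SE 0.397) and the transcriptional cofactor Mn1 at -0.99 (SE 0.211). Interferon response genes rose together (median 0.49, 28 of 32 positive, adjusted p = 9.28e-13, adjusted p = 0.0601 with an estimated correlation), with 11 members higher when adjusted over the list alone, such as Rtp4 at 0.67 (SE 0.127), Usp18 at 1.02 (SE 0.232) and Bst2 at 0.49 (SE 0.116). HSC aging genes, reported elsewhere to increase in old HSCs, rose (median 0.38, 24 of 31 positive, adjusted p = 1.02e-07, adjusted p = 0.253 with an estimated correlation), with 8 higher when adjusted over the list alone. They included clusterin (Clu) at 1.55 (SE 0.255), the tetraspanin Cd9 at 0.49 (SE 0.0890), Ehd3 at 1.87 (SE 0.438) and the HSC surface receptor Slamf1 at 0.98 (SE 0.232). Megakaryocyte and platelet genes rose (median 0.52, 13 of 16 positive, adjusted p = 1.49e-05, adjusted p = 0.0882 with an estimated correlation), with 0 called when adjusted over the list alone. Pf4, a platelet chemokine, was at 1.09 (SE 0.263) and Vwf at 1.32 (SE 0.455). The HSC aging and megakaryocyte lists share 3 tested genes, Itga2b, Itgb3 and Vwf.

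Nuclear genes of oxidative phosphorylation rose by a small amount (median 0.25, 72 of 82 positive, adjusted p = 2.14e-17, adjusted p = 0.253 with an estimated correlation), as did ribosomal protein genes (median 0.22, 82 of 86 positive, adjusted p = 7.56e-17, adjusted p = 0.509 with an estimated correlation). Mitochondrially encoded genes did not pass (median 0.03, 7 of 13 positive, adjusted p = 0.697). Neither of the 2 lists called had a member called when adjusted over the list alone. Examples are Atp5g1 at 0.40 (SE 0.0870), Cox7a2 at 0.34 (SE 0.0787) and Rpl26 at 0.35 (SE 0.0883). Immediate early genes fell (median -0.30, 13 of 21 negative, adjusted p = 2.48e-04, adjusted p = 0.131 with an estimated correlation), 4 of them when adjusted over the list alone, including Egr1 at -0.96 (SE 0.176) and Dusp1 at -0.89 (SE 0.222). NF-kB and inflammatory genes fell (median -0.19, 15 of 21 negative, adjusted p = 1.81e-05, adjusted p = 0.139 with an estimated correlation), 3 of them when adjusted over the list alone, such as the chemokine Ccl3 at -2.97 (SE 0.623). Lymphoid genes fell (median -0.66, 8 of 9 negative, adjusted p = 0.00335, adjusted p = 0.405 with an estimated correlation), 1 of them when adjusted over the list alone. Dntt, a lymphoid DNA polymerase, went from 2.69 ± 2.53 CPM (5.59, 0.957 and 1.53 in Vector replicates 1 to 3) to 0. Granulocyte and monocyte genes fell (median -1.27, 10 of 11 negative, adjusted p = 0.00401, adjusted p = 0.195 with an estimated correlation), with 0 called when adjusted over the list alone and Csf3r at 26.1 ± 5.83 CPM in Vector and 13.4 ± 3.62 in PUS10-OE. Other members with the lowest p were near the floor. Csf1r went from 2.80 ± 0.229 to 0.436 ± 0.611 CPM, Irf8 from 3.32 ± 2.74 to 0.893 ± 0.642 and Mpo from 2.31 ± 1.32 to 0.445 ± 0.771.

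The remaining 4 lists were called but each lost the call without some single library. G2/M genes rose (median 0.12, 22 of 28 positive, adjusted p = 1.08e-04, adjusted p = 0.709 with an estimated correlation), with 5 higher when adjusted over the list alone, among them Cenpf at 0.72 (SE 0.118) and Ube2c at 0.67 (SE 0.167). The adjusted p was 0.139 without Vector replicate 1 and 0.0897 without PUS10-OE replicate 1. Pseudouridine synthases passed upward (mean 0.15, median -7.5e-06, 7 of 15 positive, adjusted p = 0.0208, adjusted p = 0.441 with an estimated correlation), so the median and the mean differ in sign. Of these 15 genes 3 were higher when adjusted over the list alone, Pus10 itself, the gene the experiment targets, and the box H/ACA proteins Nhp2 at 0.44 (SE 0.0757) and Nop10 at 0.32 (SE 0.0944). Their adjusted p was 0.0954 without Vector replicate 1 and 0.0576 without PUS10-OE replicate 3. Erythroid genes rose (median 0.37, 9 of 11 positive, adjusted p = 0.0384, adjusted p = 0.357 with an estimated correlation), with adjusted p = 0.251 without Vector replicate 2 and 0.0561, 0.0877 and 0.0576 without PUS10-OE replicates 1, 2 and 3. Cytokine receptors and niche adhesion genes fell (median -0.07, 15 of 23 negative, adjusted p = 0.0245, adjusted p = 0.249 with an estimated correlation), with Flt3 at -1.30 (SE 0.345) and Kit at -0.37 (SE 0.132). Their adjusted p was 0.0939 without PUS10-OE replicate 1 and 0.102 without PUS10-OE replicate 2. HSC identity genes (median 0.05, adjusted p = 0.555), microRNA processing genes (adjusted p = 0.353) and reported miR-139 targets (adjusted p = 0.809) did not pass.

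Knockdown of miR-139 was accompanied by higher megakaryocyte, HSC aging and HSC identity genes and by lower multipotent progenitor and lymphoid genes. Pf4 (ENSMUSG00000029373.7, chromosome 5, 90772435 to 90773383, plus strand), a platelet chemokine, rose from 68.5 ± 47.2 to 1356 ± 615 CPM (SD, n = 6 each), a 19.8-fold difference. The receptor tyrosine kinase Flt3 (ENSMUSG00000042817.15, chromosome 5, 147330741 to 147400489, minus strand), a marker of multipotent and lymphoid progenitors, fell from 142 ± 28.6 to 40.7 ± 10.2 CPM (log2 fold change -1.80, SE 0.179, edgeR adjusted p = 3.52e-04). Of 13295 genes tested 361 passed, 187 higher and 174 lower, with a median absolute fold of 1.87, in which 1 gene with a group at 0 counts at its fitted value. DESeq2 called 1100 genes, and edgeR with all 6 groups in 1 fit 792. Leaving out single libraries gave 224 genes without NTC replicate 2, 196 without NTC replicate 3, 237 without NTC replicate 4, 238 without miR139-KD replicate 1 and 229 without miR139-KD replicate 2. Without NTC replicate 6 and miR139-KD replicate 1 together, the least correlated library of each group, 212 were called, 182 of them among the 361.

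**Figure D2:**
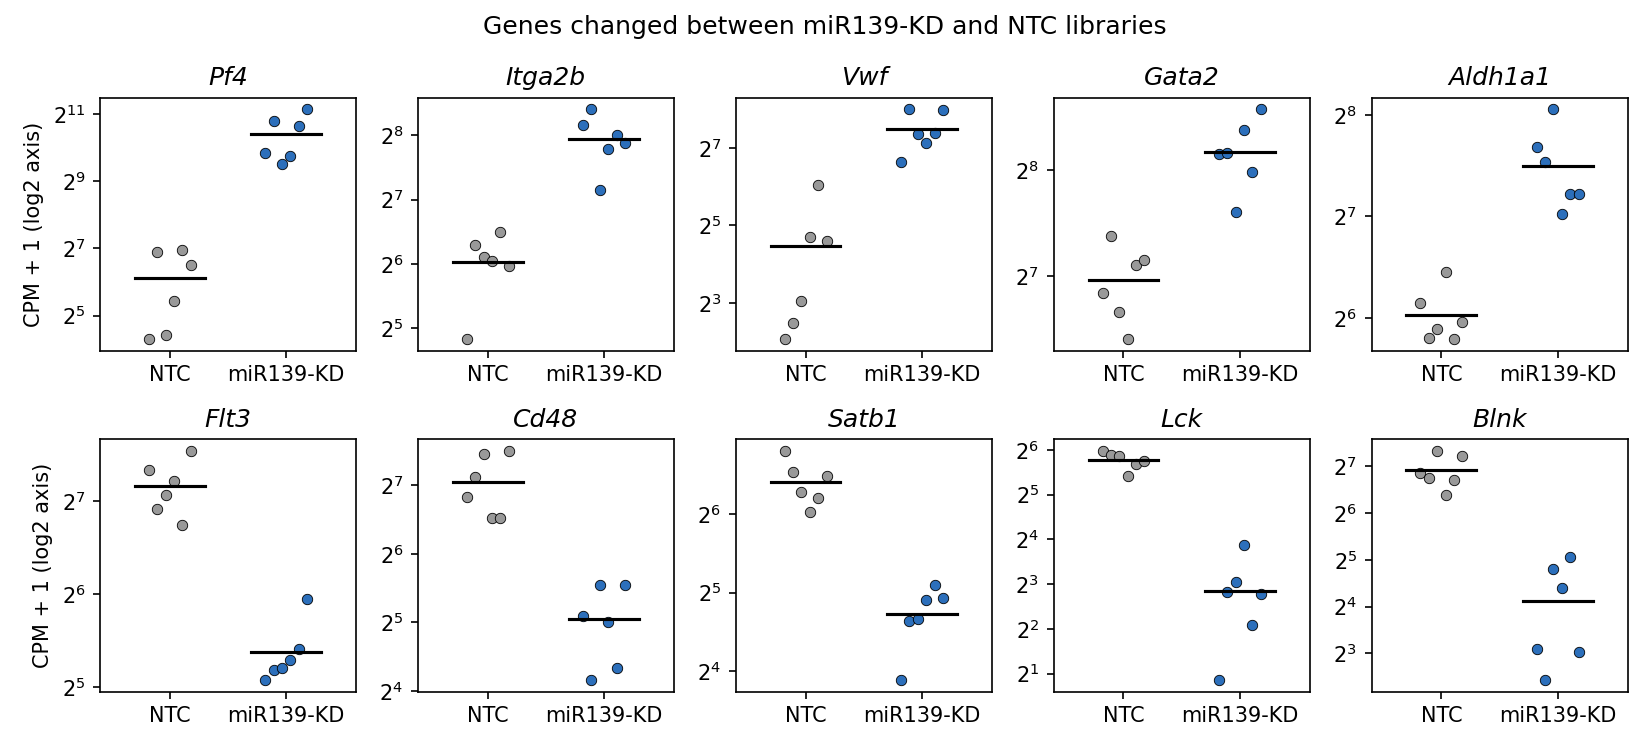
Levels of 10 genes in each NTC and miR139-KD library, as CPM + 1 on a log2 axis whose range differs between panels. Points are libraries (n = 6 per group) and lines are group means. Pf4, Itga2b, Vwf, Gata2 and Aldh1a1 were higher and Flt3, Cd48, Satb1, Lck and Blnk lower in all 6 knockdown libraries than in every control library.

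Megakaryocyte and platelet genes rose as a group (median 2.02, 14 of 14 positive, adjusted p = 3.25e-26, adjusted p = 0.00200 with an estimated correlation). Over all genes 11 members were called, and adjusted over the list alone 13. The integrin Itga2b rose from 64.5 ± 20.8 to 246 ± 65.9 CPM (1.93, SE 0.250), the von Willebrand receptor subunit Gp9 from 24.4 ± 8.97 to 111 ± 46.1 (2.19, SE 0.313), and Nrgn from 24.3 ± 5.15 to 65.4 ± 19.8 (1.43, SE 0.222). HSC aging genes rose (median 1.38, 27 of 27 positive, adjusted p = 6.16e-19, adjusted p = 0.00654 with an estimated correlation), with 10 members called over all genes and 14 adjusted over the list alone. Aldh1a1, a retinaldehyde dehydrogenase, rose from 64.1 ± 12.3 to 180 ± 49.9 CPM (1.49, SE 0.181), the caveolar protein Cavin2 from 11.5 ± 6.94 to 88.4 ± 24.7 (2.94, SE 0.418) and Cd9 from 85.3 ± 30.6 to 222 ± 38.3 (1.38, SE 0.211). The HSC aging and megakaryocyte lists share 3 tested genes, and the HSC aging and HSC identity lists share 1. HSC identity genes rose (median 0.84, 25 of 27 positive, adjusted p = 8.82e-15, adjusted p = 0.0473 with an estimated correlation), with 8 members called over all genes and, adjusted over the list alone, 17 higher and 1 lower. The transcription factor Gata2 rose from 123 ± 30.0 to 289 ± 64.4 CPM (1.23, SE 0.180). Among the largest rises were also the cyclooxygenase Ptgs1 at 2.32 (SE 0.236), the granule-trafficking GTPase Rab27b at 3.00 (SE 0.476), Bex4 at 2.31 (SE 0.455) and Vwf at 3.06 (SE 0.608, adjusted p = 0.0150). The highest Vwf value of NTC was in replicate 5, at 64.5 CPM.

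Multipotent progenitor genes fell as a group (median -1.62, 11 of 11 negative, adjusted p = 6.66e-30, adjusted p = 0.00654 with an estimated correlation), 9 over all genes and 11 adjusted over the list alone. The surface receptor Cd48 fell from 131 ± 39.7 to 31.9 ± 12.4 CPM (-2.04, SE 0.277), and the chromatin organiser Satb1 from 84.5 ± 16.7 to 25.6 ± 6.79 (-1.72, SE 0.212). Lymphoid genes fell (median -2.49, 18 of 18 negative, adjusted p = 6.19e-23, adjusted p = 0.0494 with an estimated correlation), 7 over all genes and 17 adjusted over the list alone. The T cell kinase Lck fell from 53.6 ± 7.25 to 6.14 ± 4.35 CPM (-3.12, SE 0.455), the B cell adaptor Blnk from 119 ± 29.4 to 16.4 ± 11.7 (-2.86, SE 0.436), Lax1 from 21.6 ± 7.77 to 3.59 ± 0.959 (-2.59, SE 0.354) and the B cell receptor subunit Cd79a from 326 ± 92.4 to 46.0 ± 33.9 CPM (-2.82, adjusted p = 0.0112). Further large falls were those of Bcat1, an enzyme of branched-chain amino acid breakdown, from 20.2 ± 7.72 to 0.108 ± 0.266 CPM, of Drc7 at -3.74 (SE 0.581) and of Bfsp2 at -2.78 (SE 0.318). Markers of other lineages, chosen after their values were seen, varied widely within both groups. Hba-a1 ranged from 14.9 to 3944 CPM in NTC and from 74.4 to 3965 in miR139-KD, Elane from 0 to 438 and from 0.506 to 2001, and Igkc from 0 to 9060 and from 1.82 to 9120.

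Ribosomal protein genes rose slightly (median 0.17, 75 of 86 positive, adjusted p = 1.23e-05, adjusted p = 0.573 with an estimated correlation), with 12 higher over all genes and, adjusted over the list alone, 25 higher and 2 lower. Rpsa was at 0.40 (SE 0.0644) and Rps14 at 0.30 (SE 0.0520). Glycolysis genes fell (median -0.24, 16 of 20 negative, adjusted p = 0.00950, adjusted p = 0.139 with an estimated correlation), 1 over all genes and, adjusted over the list alone, 6 lower and 1 higher. Pfkl, at -0.55 (SE 0.147), had an adjusted p of 0.0634 over all genes. Without the least correlated library of each group the adjusted p of glycolysis was 0.0501. G1/S genes fell (median -0.21, 21 of 26 negative, adjusted p = 0.00950, adjusted p = 0.573 with an estimated correlation, 0 members adjusted over the list alone), with adjusted p = 0.0504 without miR139-KD replicate 4. MHC class I genes rose (median 0.10, 11 of 16 positive, adjusted p = 0.0245, adjusted p = 0.573 with an estimated correlation), 3 over all genes and 5 adjusted over the list alone, with H2-Q7 at 0.78 (SE 0.144), a member of a multigene family whose reads may be split. The adjusted p of that list was 0.0908 without NTC replicate 4 and 0.0782 without miR139-KD replicate 2. Heat shock genes fell (median -0.18, 10 of 12 negative, adjusted p = 0.0286, adjusted p = 0.509 with an estimated correlation), 2 over all genes and 3 adjusted over the list alone, including the co-chaperone Dnaja1 at -0.54 (SE 0.106). Their adjusted p was 0.0715 and 0.0903 without NTC replicates 3 and 4, and 0.0782, 0.0575 and 0.0687 without miR139-KD replicates 2, 3 and 4. Erythroid (median 0.23, adjusted p = 0.523), granulocyte (0.07, adjusted p = 0.819), interferon (adjusted p = 0.470), microRNA processing (adjusted p = 0.303) and pseudouridine synthase genes (adjusted p = 0.191) did not pass as lists in camera. In fry microRNA processing genes passed upward (median 0.15, 14 of 19 positive, fry adjusted p = 0.0153). The RNA helicase Ddx5 nevertheless fell by 0.46 (SE 0.0915, adjusted p = 0.0148) and the pseudouridine synthase Pusl1 by 1.55 (SE 0.311, adjusted p = 0.0162).

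The gene that carries miR-139, Pde2a, was near the floor in all 24 libraries (at most 1.58 CPM) and was not tested, and no reads were counted on the microRNA precursor. Reported miR-139 targets did not pass as a list (median 0.16, adjusted p = 0.180), with 1 member called over all genes and, adjusted over the list alone, 4 higher and 3 lower. That member, the small GTPase Rap1b, rose from 129 ± 14.5 to 334 ± 88.7 CPM (1.37, SE 0.157, adjusted p = 4.92e-04). Notch1 had a log2 fold change of -2.02 (SE 0.551, adjusted p = 0.0677) and Zeb2 of 0.55 (SE 0.170, adjusted p = 0.107). Of 11108 genes with a searched 3' untranslated region, 1548 held a match to the miR-139-5p seed (ACTGTAG). Their median log2 fold change lay 0.018 below that of matched genes without a site (difference -0.018, SD of draws 0.0138, two-sided permutation p = 0.182 from 10000 draws). For miR-139-3p (CGTCTCC, 514 genes) the difference was -0.013 (SD of draws 0.0248, permutation p = 0.599). Without matching, the differences were above 0, at 0.026 for miR-139-5p (permutation p = 0.0814) and 0.021 for miR-139-3p (permutation p = 0.416). With only the longer matches ACTGTAGA and CGTCTCCA they were -0.0023 and -0.015 (permutation p = 0.918 and 0.720).

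**Figure D3:**
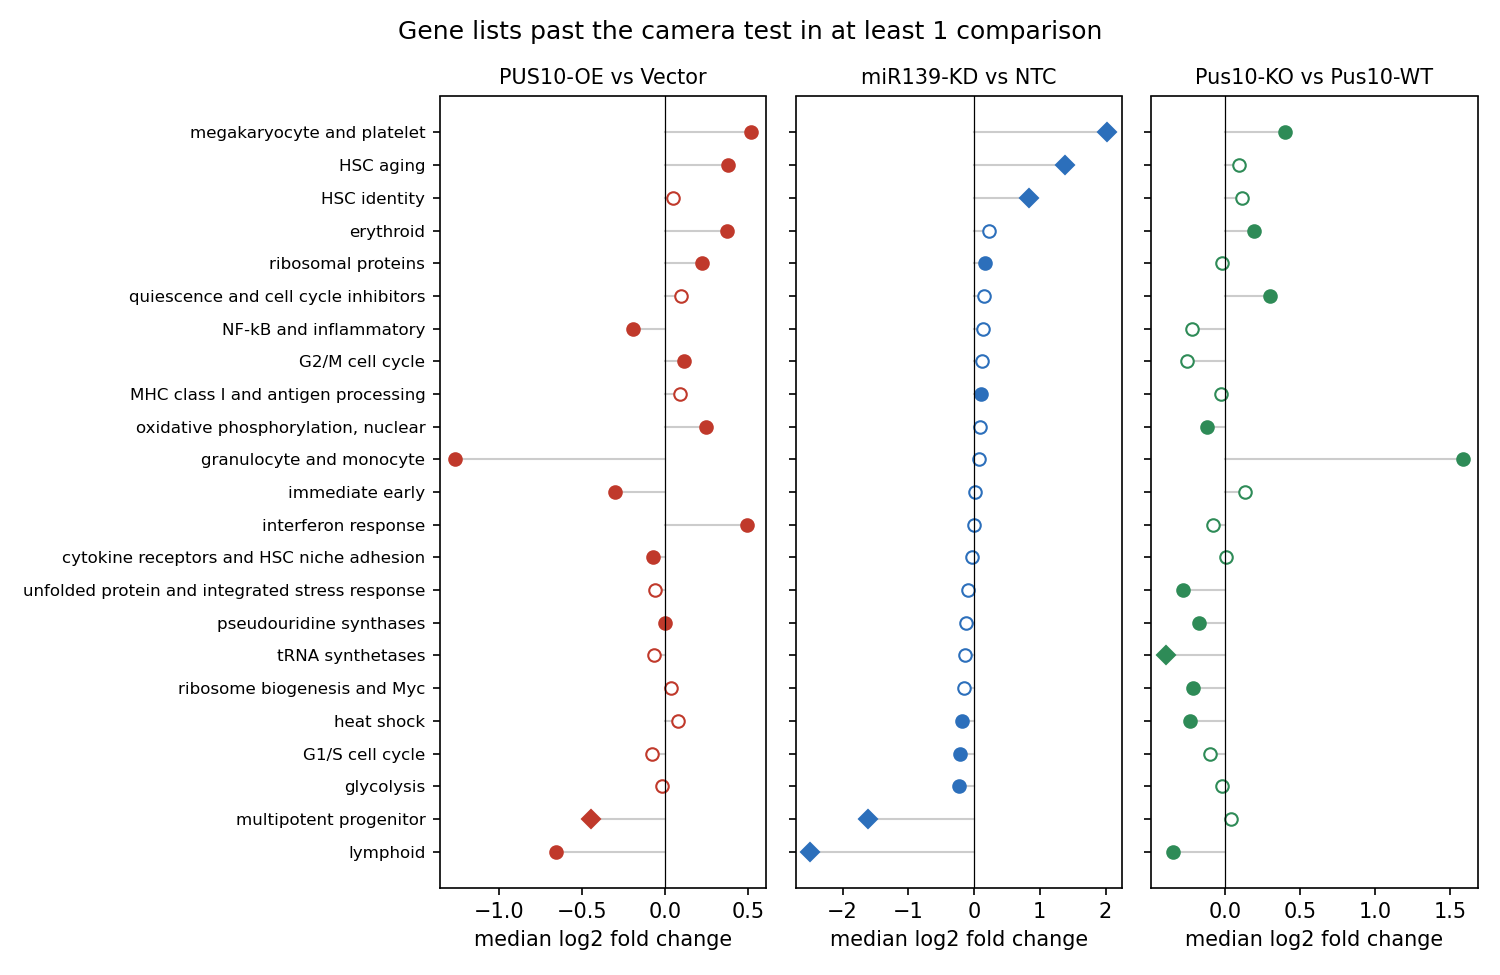
Median log2 fold change of the members of each gene list (x axis, whose range differs between panels) for the lists that passed camera in at least 1 of the 3 comparisons. Filled circles passed with the preset correlation, diamonds also with an estimated correlation, and open circles did not pass. The longest lines are those of the lymphoid (-2.49), megakaryocyte (2.02) and multipotent progenitor (-1.62) lists in miR139-KD.

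In the libraries labelled Pus10-KO, immunoglobulin transcripts were lower and Sox6 and Tsc22d3 higher than in Pus10-WT, where directions are drawn although the targeted transcript was not lower. Ighm (ENSMUSG00000076617.9, chromosome 12, 113418558 to 113422730, minus strand), the immunoglobulin M heavy chain, fell from 10374 ± 4644 to 34.8 ± 9.26 CPM (SD, n = 3 each; log2 fold change -8.22, SE 0.468, edgeR adjusted p = 0.00293). Jchain, which links immunoglobulin polymers, fell from 2150 ± 1603 to 1.62 ± 1.84 CPM, and Cd79a from 36.3 ± 4.43 to 0, at least 550-fold. The transcription factor Sox6 (ENSMUSG00000051910.13, chromosome 7, 115470872 to 116038796, minus strand) rose from 32.1 ± 3.80 to 113 ± 5.49 CPM (1.82, SE 0.171), and Tsc22d3, a glucocorticoid-induced leucine zipper protein on chromosome X, from 482 ± 58.7 to 1094 ± 111 (1.18, SE 0.121). The aspartic protease Ctse fell from 412 ± 54.0 to 107 ± 23.9 CPM (-1.94, SE 0.188), and Prg2, an eosinophil granule protein, from 26.8 ± 6.63 to 0, at least 406-fold. Apart from Ighm, each of these genes had an edgeR adjusted p of 0.0238.

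Of 14657 genes tested 9 passed, 2 higher and 7 lower, and 1006 had an unadjusted p under 0.05. The other calls were the light chain genes Iglc2, at least 683-fold lower, and Iglc3, from 19.9 ± 5.17 to 0.0181 ± 0.0313 CPM, whose reads near-identical copies may share. DESeq2 called 237 genes, limma-voom 3, edgeR with a filter of 10 CPM 14, and edgeR with all 6 groups in 1 fit 15, which hold only 2 of the 9. Without Pus10-KO replicate 2 or 3, 0 genes were called, without Pus10-WT replicate 1, 2, and without Pus10-WT replicate 2 or 3, 1 each. Without Pus10-KO replicate 1, 10 were called, 5 higher and 5 lower, of which 4 are among the 9 (Ighm, Iglc2, Cd79a and Prg2) and none is Sox6 or Tsc22d3. Ighm was lost only without Pus10-KO replicates 2 and 3 (adjusted p = 0.0561 and 0.0569). Tsc22d3 was lost without any 1 library, with adjusted p = 0.224, 0.123 and 0.181 without Pus10-WT replicates 1 to 3 and 0.0941, 0.147 and 0.0933 without Pus10-KO replicates 1 to 3. In the same order of libraries, Ctse was lost at 0.142, 0.123, 0.181, 0.113, 0.0772 and 0.0690, Jchain at 0.102, 0.307, 0.178, 0.0645, 0.248 and 0.0690, and Iglc3 at 0.142, 0.123, 0.284, 0.0601, 0.108 and 0.0934. Without Pus10-WT replicates 1 to 3 and Pus10-KO replicates 2 and 3, Iglc2 was lost at 0.142, 0.123, 0.181, 0.0772 and 0.0690, and Prg2 at 0.142, 0.227, 0.284, 0.0895 and 0.0690. The groups did not overlap in 2001 genes, or 13.7%, where chance gives 10%. Not called were the anchoring protein Akap13 at 0.69 (SE 0.0856, adjusted p = 0.0646) and Rin3 at 1.70 (SE 0.230, adjusted p = 0.106). Markers of other lineages ranged widely. Igkc, chosen after its values were seen, was at 9839 to 13468 CPM in Pus10-WT and at most 15.0 in Pus10-KO, Hba-a1 at 23.6 to 122 and 135 to 2438, and Elane at 0 to 1.64 and 1.52 to 1307.

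**Figure D4:**
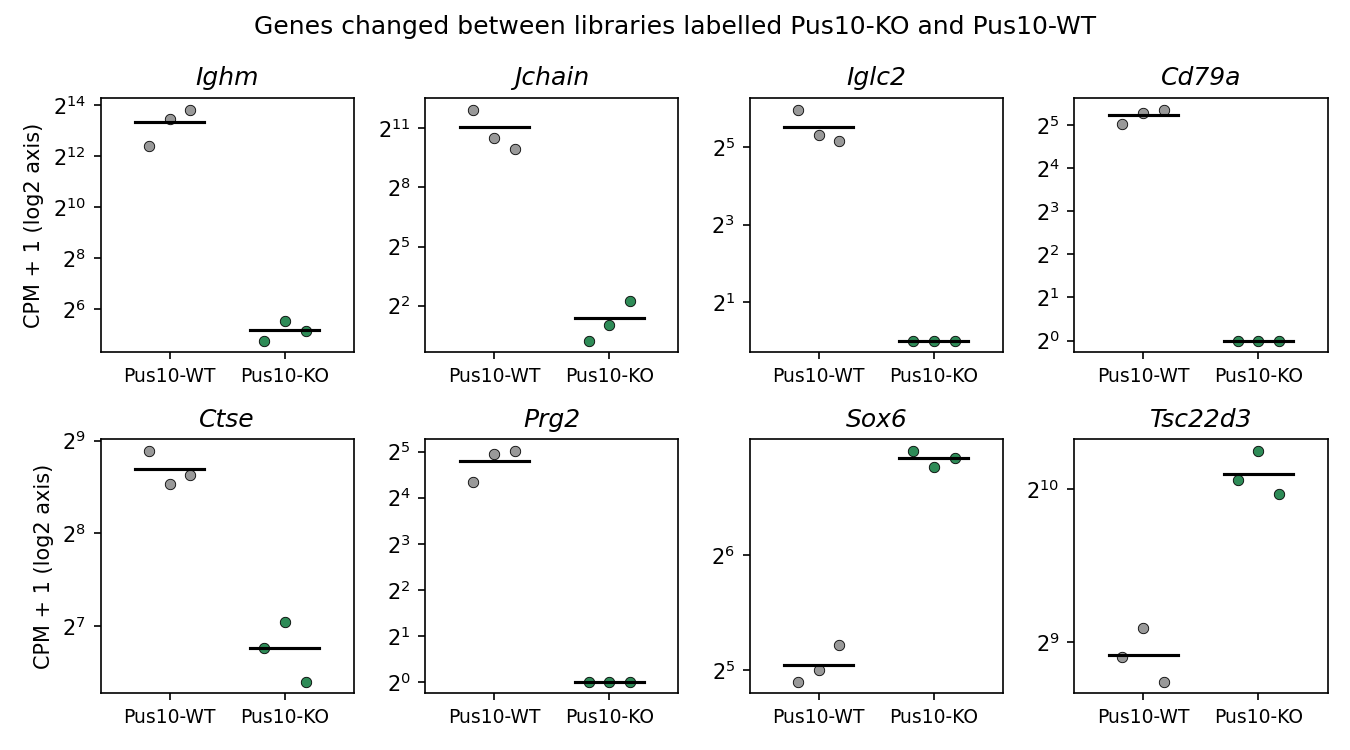
Levels of 8 of the 9 called genes in each Pus10-WT and Pus10-KO library, as CPM + 1 on a log2 axis whose range differs between panels. Points are libraries (n = 3 per group) and lines are group means. Sox6 and Tsc22d3 were higher in the libraries labelled Pus10-KO and the other 6 genes lower, with no overlap between groups.

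Of 36 lists tested 11 passed in these libraries, 4 upward and 7 downward. Aminoacyl-tRNA synthetase genes, whose enzymes charge tRNAs, fell together (median -0.39, 20 of 20 negative, adjusted p = 9.62e-10), the 1 call that held, with adjusted p = 0.0473 with an estimated correlation. Of its members 0 passed over all genes and 1 adjusted over the list alone. Examples are Eprs at -0.65 (SE 0.142), Mars at -0.80 (SE 0.246), Kars at -0.48 (SE 0.165) and Farsa at -0.47 (SE 0.143). In the same libraries all 14 tested plasma and B cell genes other than immunoglobulin, listed after the pattern was seen, also stood lower, such as Derl3 at 1.21 ± 2.09 CPM against 25.6 ± 11.8 and Txndc5 at 106 ± 32.3 against 204 ± 49.1. Unfolded protein and integrated stress response genes fell (median -0.28, 18 of 24 negative, adjusted p = 1.53e-05, adjusted p = 0.232 with an estimated correlation), 3 of them adjusted over the list alone. They include Xbp1, a secretory-pathway transcription factor abundant in plasma cells, at -0.88 (SE 0.167), Creld2 at -0.78 (SE 0.188), the asparagine synthetase Asns at -0.99 (SE 0.265) and Manf at -0.62 (SE 0.201). Lymphoid genes fell (median -0.35, 8 of 12 negative, adjusted p = 5.32e-11, adjusted p = 0.0601 with an estimated correlation), with Ighm and Cd79a called over all genes and the same count, 2, adjusted over the list alone. Heat shock genes fell (median -0.24, 12 of 14 negative, adjusted p = 0.00533, adjusted p = 0.240 with an estimated correlation, 0 adjusted over the list alone), with Hspa8 at -0.38 (SE 0.0954). Granulocyte and monocyte genes rose (median 1.58, 16 of 17 positive, adjusted p = 2.04e-04, adjusted p = 0.426 with an estimated correlation), with 0 called over all genes or adjusted over the list alone and Elane at 0.609 ± 0.949 CPM in Pus10-WT and 669 ± 646 in Pus10-KO.

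The other 6 calls were each lost without some single library. Genes of quiescence and cell cycle inhibition rose (median 0.30, 14 of 17 positive, adjusted p = 0.00439, adjusted p = 0.215 with an estimated correlation), 1 of them adjusted over the list alone, with Cdkn1b at 1.36 (SE 0.312) and Cdkn1c at 1.82 (SE 0.497), and had adjusted p = 0.0679 without Pus10-KO replicate 1. Erythroid genes rose (median 0.19, 12 of 21 positive, adjusted p = 0.00950, adjusted p = 0.709 with an estimated correlation), with adjusted p = 0.231 without Pus10-KO replicate 1 and a downward direction (adjusted p = 0.457) without Pus10-WT replicate 2. Megakaryocyte and platelet genes rose (median 0.40, 11 of 14 positive, adjusted p = 0.0289, adjusted p = 0.253 with an estimated correlation), 2 of them adjusted over the list alone, the integrin Itgb3 at 1.03 (SE 0.219) and Nrgn at 1.12 (SE 0.284). Their adjusted p was 0.0587, 0.0998 and 0.0985 without Pus10-WT replicates 1, 2 and 3, and 0.294 and 0.203 without Pus10-KO replicates 1 and 3. Nuclear oxidative phosphorylation genes fell (median -0.12, 63 of 82 negative, adjusted p = 0.00382, adjusted p = 0.734 with an estimated correlation), as did ribosome biogenesis genes (median -0.21, 19 of 24 negative, adjusted p = 0.00484, adjusted p = 0.509 with an estimated correlation), neither with a member adjusted over the list alone. Without Pus10-WT replicate 3 their adjusted p was 0.159 and 0.187, and without Pus10-KO replicate 3 0.168 and 0.0858. Pseudouridine synthases fell (median -0.18, 10 of 15 negative, adjusted p = 0.0331, adjusted p = 0.253 with an estimated correlation, 0 adjusted over the list alone), with Trub2 at -1.11 (SE 0.364). Their adjusted p was 0.0555 and 0.0766 without Pus10-WT replicates 2 and 3, and 0.0998 and 0.155 without Pus10-KO replicates 1 and 2. HSC identity (adjusted p = 0.232), HSC aging (adjusted p = 0.470), microRNA processing (adjusted p = 0.525) and reported miR-139 target genes (adjusted p = 0.517) did not pass. G2/M genes did not pass either (adjusted p = 0.916), but passed downward without Pus10-WT replicate 2 (adjusted p = 2.42e-05) and upward without Pus10-WT replicate 3 (adjusted p = 0.00485).

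Fold changes were then compared across genes between experiments, which share no libraries. Genes are not independent, so each correlation was set against 100 pairs of splits of the samples, the real pair included. Most of the other pairs regrouped both experiments at once and so also removed the real knockdown grouping. A small share therefore does not test whether the changes of 1 experiment recur in another. With the knockdown grouping kept, PUS10-OE and Pus10-KO have 10 splits each, too few for a share under 0.05. PUS10-OE and miR139-KD had a Pearson r of 0.145 and a Spearman rho of 0.130 over 12615 genes, and 1 of the 100 pairs was as large (highest other 0.0843, share 0.01, adjusted 0.03 over 3 correlations). For miR139-KD and Pus10-KO r was 0.0983 and rho 0.151 over 12681 genes, with 2 of 100 pairs as large (highest other 0.102, share 0.02, adjusted 0.03). That value was 0.0360 without Pus10-WT replicate 1, 0.0645 without Pus10-WT replicate 2 and 0.0434 without Pus10-KO replicate 1. For PUS10-OE and Pus10-KO r was -0.011 and rho 0.017 over 13365 genes, with 63 of 100 pairs as large. Only 2 genes were called in more than 1 experiment: Cd79a was lower in both miR139-KD and the libraries labelled Pus10-KO, where independent lists would share 0.0767 genes, and Sox6 higher in both, where they would share 0.0292. In the libraries labelled Pus10-KO Cd79a fell along with immunoglobulin and other plasma and B cell genes. Its overlap therefore does not show an effect shared with the knockdown. Sox6 rose from 24.2 ± 6.15 to 55.3 ± 21.6 CPM in miR139-KD (1.19, SE 0.294, adjusted p = 0.0454). That call was kept without NTC replicate 6 or miR139-KD replicate 6 and lost without each of the other 10 libraries in turn, with adjusted p = 0.0841, 0.0989, 0.0891, 0.0702 and 0.0822 without NTC replicates 1 to 5 and 0.0726, 0.0965, 0.0749, 0.0856 and 0.0582 without miR139-KD replicates 1 to 5. In the libraries labelled Pus10-KO the Sox6 call was lost without any 1 library, with adjusted p = 0.142, 0.140 and 0.178 without Pus10-WT replicates 1 to 3 and 0.0787, 0.114 and 0.0934 without Pus10-KO replicates 1 to 3. The Cd79a call there was kept only without Pus10-KO replicate 1, with adjusted p = 0.142, 0.123 and 0.181 without Pus10-WT replicates 1 to 3 and 0.0691 and 0.0569 without Pus10-KO replicates 2 and 3. In miR139-KD the Cd79a call was kept without each library in turn and had adjusted p = 0.0515 without the least correlated library of each group.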

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

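The tests of explanations and of splits below were chosen only after the results were seen, except the test of seed sites among called genes. Of 78 values tested for a library standing apart, about 1 in 20 would be marked by chance.

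In NTC replicate 1, 11.8% of reads lay outside annotated genes, against 8.68% in the next library. Vwf was at 64.5 CPM in NTC replicate 5, against 24.8 in the next. Cecr2 was at 18.1 CPM in NTC replicate 4, where the other 5 libraries had 38.1 to 49.9. Bcat1 was at 0.651 CPM in miR139-KD replicate 3 and at 0 in the other 5 libraries. The score of MHC class I genes was -0.186 in miR139-KD replicate 6, against 0.0751 in the next. Outside the gene counts, the lowest share of ambiguous reads in PUS10-OE, 6.66%, was above the highest in Vector, 6.60%.

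Megakaryocyte genes rose and progenitor and lymphoid genes fell in miR139-KD. Megakaryocytes or platelets mixed in would dilute stem and progenitor genes alike. The progenitor score minus that of 12 HSC-restricted genes was lower by 2.25 on the log2 scale (difference -2.25, two-sided exact permutation p = 0.00216). That p adds no support, because the values of the progenitor and HSC identity lists had been seen. The 12 HSC-restricted genes had a median log2 fold change of 0.736, with 11 higher and 0 called. They were not diluted, which argues against such a mixture as the whole cause of the progenitor part. A lower share of lymphoid-primed progenitors as the only change stays open. It was predicted to raise other lineages alike. The megakaryocyte score rose 1.92 above the mean of the erythroid and granulocyte scores (exact permutation p = 0.00216, the smallest that 924 permutations can give). That contrast cannot decide it, because the list values had been seen and markers of the other lineages ranged widely within both groups. The megakaryocyte list also shares 3 tested genes with the HSC aging list, so its score is not specific to that lineage. With every library thinned to 1 depth 27 of the 27 called members of the 3 lists were still called, and with offsets for GC content and length 26, which argues against both as the whole cause. For the megakaryocyte part, added RNA stays open and cannot be told apart from a change in the sorted cells: 7 of 12 genes of mature megakaryocytes and platelets were tested (4 also in the megakaryocyte list), with a median log2 fold change of 1.43, 6 higher and 1 called, Nrgn, while the platelet chemokine Ppbp reached 7.81 ± 8.79 CPM beside 1356 ± 615 for Pf4. Of the 182 searched genes called higher, 26 held a miR-139-5p site (14.3%), against 13.9% of uncalled genes (odds ratio 1.03, 95% interval 0.651 to 1.58, Fisher's exact p = 0.830). Most genes called higher held no site, but so did most uncalled genes, so that majority decides nothing. Loss of repression through such sites stays open as a contribution to the rises, because the interval reaches 1.58.

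Immunoglobulin transcripts were high in Pus10-WT and near 0 in the libraries labelled Pus10-KO. Plasma cells, B-lineage cells or their RNA may account for this: of 18 listed plasma and B cell genes other than immunoglobulin, chosen after the pattern was seen, 14 were tested and all 14 were higher in Pus10-WT, 9 without overlap between groups and 1 called (3 are also in the lymphoid list). Among them Derl3 was at 25.6 and 1.21 CPM, Mzb1 at 6.60 and 0, Ly6d at 37.5 and 0 and Txndc5 at 204 and 106. Whether the sort removed such cells cannot be judged, because the labels do not give its markers. Loss of immunoglobulin RNA from stem cells lacking Pus10 cannot be told apart from it in this experiment: the median of Igkc was 1.79 CPM in the libraries labelled Pus10-KO and 0 in every Vector and PUS10-OE library, and 3 of the 18 libraries of the other experiments exceeded 1000 CPM (NTC replicate 5 with 9060, miR139-KD replicates 5 and 6 with 9120 and 2737).

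The Pus10 transcript was at the wild-type level in the libraries labelled Pus10-KO. A deletion that leaves the rest of the transcript counted stays open: the mean was 124% of Pus10-WT, and 1 count per gene cannot show missing exons. Exchanged labels within the experiment stay open too: the lowest of the 6 libraries stood at 52.1% of the highest, but such a deletion would leave no library low whatever the labels.

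Among splits of the samples, 1 of 100 drawn for miR139-KD, the real one, gave 361 called genes (highest other 1), so no other split drawn came near that count. This does not tell the knockdown apart from a difference in animals, sort or day between the groups. As many called lists as the real 10 came from 24 of the 100 splits (highest other 15), so chance is not excluded for the number of lists. By list, 1 of the 100 splits, the real one, gave the lowest camera p (preset correlation) for megakaryocyte, multipotent progenitor, lymphoid, HSC aging and HSC identity genes. For G1/S genes 16 of the 100 gave a p as small, for MHC class I and heat shock genes 13 each and for ribosomal protein genes 5, so chance is not excluded there. For glycolysis genes 3 did. In the other 2 experiments 10 splits are too few for a share under 0.05: PUS10-OE gave 0 genes in all 10 splits (highest other 0) and 14 lists in 1 (highest other 10), and Pus10-KO 9 genes in 1 (highest other 0) and 11 lists in 1 (highest other 10). By list, a p as small came from 4 of the 10 splits, the real one included, for G2/M genes in PUS10-OE. Ribosomal protein and lymphoid genes there had 2 each. In Pus10-KO erythroid genes had 5, granulocyte genes 4 and nuclear oxidative phosphorylation genes 3. For the other called lists the real split gave the lowest p.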

How the results depend on the processing

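Removal of the least correlated libraries, thinning, GC and length offsets and removal of 397 immunoglobulin genes were tests chosen after seeing the data. No named gene's called direction reversed under any alternative. Of 47 named genes called in miR139-KD, 25 kept the call in all 23 settings and 33 in every fit without 1 library; of the 9 in Pus10-KO, 0 did. Over all named genes 122 results became weaker and 24 stronger in miR139-KD, 71 and 28 in Pus10-KO, and 0 and 54 in PUS10-OE. Unless a reason is given, the cause was not tested.

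For miR139-KD the 361 genes (187 higher, 174 lower) became 1100 (544, 556) with DESeq2, 792 (364, 428) with all 6 groups in 1 fit and 212 (110, 102) without NTC replicate 6 and miR139-KD replicate 1, where fewer samples were fitted; limma-voom called 263 lower. For Pus10-KO the 9 genes (2 higher, 7 lower) became 237 (129, 108) with DESeq2, 15 (9 higher; 2 of the 9 kept) with all 6 groups, 14 (5 higher; 7 kept) with a filter of 10 CPM and 3 (1 lower; 3 kept) with limma-voom. For PUS10-OE the 0 genes became 251 (124, 127) with DESeq2, 12 (8, 4) with a filter of 10 CPM, where fewer genes are tested, and 5 (5 higher) with all 6 groups; 1215 had an unadjusted p under 0.05. Pus10 in PUS10-OE passed with log2 fold changes of 1.75 in DESeq2 (adjusted p = 7.46e-15), 1.75 with the 10 CPM filter (adjusted p = 0.00108) and 1.78 with all 6 groups (adjusted p = 0.00311).

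Of the lists called, an estimated correlation kept 1 of 14 in PUS10-OE, 5 of 10 in miR139-KD and 1 of 11 in Pus10-KO. Over all lists tested, fry called 4, 9 and 2. Its calls in miR139-KD include microRNA processing (fry adjusted p = 0.0153) and Notch and Wnt genes (fry adjusted p = 0.0330), which camera did not call. Among genes with a mean log2 CPM of at least 4, correlations of fold changes were 0.199 (PUS10-OE and miR139-KD), 0.184 (miR139-KD and Pus10-KO) and 0.0258 (PUS10-OE and Pus10-KO).

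Without single libraries, miR139-KD gave 196 (without NTC replicate 3; 184 of them among the 361) to 340 genes, 101 to 173 higher and 95 to 185 lower, with 224 without NTC replicate 2, 237 without NTC replicate 4, and 238 and 229 without miR139-KD replicates 1 and 2. Pus10-KO gave 0 (without Pus10-KO replicate 2 or 3) to 10 genes (without Pus10-KO replicate 1), 0 to 5 higher and 0 to 5 lower, with 2, 1 and 1 without Pus10-WT replicates 1, 2 and 3. The correlation of miR139-KD with Pus10-KO ranged from 0.0360 to 0.111 and that of PUS10-OE with miR139-KD from 0.109 (without PUS10-OE replicate 2) to 0.139.

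With the replicate number as a block, miR139-KD gave 188 genes (84 higher, 104 lower), Pus10-KO 2 (0, 2) and PUS10-OE 0, and heat shock in miR139-KD (adjusted p = 0.0719) and megakaryocyte genes in Pus10-KO (adjusted p = 0.0707) were lost. Same-numbered libraries correlated at -0.0196 to 0.0197 after removal of group means and no number correlated best with its own, so no pairing by number was seen over all genes. A shared day or sort that touches few genes cannot be excluded this way. Igkc was at 9060 CPM in NTC replicate 5 and 9120 in miR139-KD replicate 5, but at 71.1 and 2737 in the libraries numbered 6. Simulated 2-fold changes were recovered least in Pus10-KO, in 26% of genes.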

Other observations

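The genes and gene sets of this part were chosen after their values were seen, as were the tests of the sets; the test of genes around Pus10 was fixed before its result was seen. In miR139-KD, 6 transcription factors picked by hand were called higher: Tal1 at 0.88 (SE 0.196, edgeR adjusted p = 0.0284), Fli1 at 0.85 (SE 0.197, 0.0343), Runx1 at 0.68 (SE 0.156, 0.0320), Gfi1b at 0.66 (SE 0.165, 0.0481), Nfix at 0.83 (SE 0.170, 0.0184) and Etv6 at 0.74 (SE 0.141, 0.0122). Called lower were Irf8, a factor of monocytes and dendritic cells, at -1.53 (SE 0.377, 0.0442), Tox, a factor of lymphoid development, at -1.66 (SE 0.382, 0.0325), and Myc at -0.62 (SE 0.154, 0.0460). No list of transcription factors was tested, and these genes were not refitted under the alternatives.

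A hypothesis was that the genes called in miR139-KD move the same way in the other experiments. In PUS10-OE, 139 of 184 genes called higher in the knockdown were higher (median log2 fold change 0.19, p = 0.00198 with an estimated correlation) and 102 of 164 called lower were lower (median -0.11, p = 0.0108 with an estimated correlation). The difference of medians was 0.298, against at most 0.177 in the other 9 of 10 splits, which are too few for a share under 0.05, so the values are consistent with a shared direction. In the libraries labelled Pus10-KO the difference was 0.319 (highest other split 0.208); 135 of 185 were higher (p = 0.0442 with an estimated correlation) and 109 of 162 lower (p = 0.212 with an estimated correlation), which leaves it open.

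Another hypothesis was that sequence of another strain around the targeted locus sets apart the neighbours of Pus10. The 44 tested genes within 5 Mb had a median absolute z of 0.837, against a median of 0.712 in 10000 random sets (permutation p = 0.196), with 0 called in edgeR, so this cannot be told apart from no effect. Xist was at 180 to 299 CPM in Pus10-WT and Pus10-KO and at 192 to 264 in Vector and PUS10-OE, where Ddx3y was 0 in every library. In NTC and miR139-KD Xist was at most 3.14 CPM and Ddx3y at 21.3 to 56.7.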
